A study of Mus musculus with 6 samples.

How the data were processed

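Epithelial cells were taken from the proximal, middle and distal colon of male and female wild-type C57BL/6J mice that had received no treatment. Total RNA was extracted with a column kit for small samples and made into strand-specific libraries of polyadenylated RNA, per the labels' protocols. The 6 libraries form 3 regions of 2 libraries each, with 1 male library (replicate 1) and 1 female library (replicate 2) per region. Replicate numbers follow the order of deposition and the sexes are given by the labels. The labels do not state how many mice a library holds, nor whether the regions of a sex come from the same mice.

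The values used are FPKM per gene as deposited by the authors. Per the submitters' processing notes, the tools were TopHat2 2.1.1, Bowtie2 2.2.8, SAMtools 0.1.18 and Cuffdiff 2.2.1 with the mm10 genome. Their settings, the annotation and the treatment of strand are not given in the sources used here. FPKM is not a count, so no count model was used. Read depth was estimated from the spacing of the lowest values, using genes with 1 annotated transcript longer than 1500 bases, values under 0.2 FPKM and an assumed fragment length of 200 bases. This gave 7.94, 7.89 and 7.78 M fragments for the male and 8.88, 9.85 and 9.85 M for the female proximal, middle and distal libraries. The assumed length and annotation make these approximate. A value of 0 can be a failed estimate, so genes at 0 in a whole group are described as listed at 0, without a fold.

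Values were analysed as log2(FPKM + 1). Differences on this scale understate changes of genes near 1 FPKM or lower. Genes with an FPKM of at least 1 in at least 2 libraries were kept, 11815 of 24346. limma 3.58.1 in R 4.3.3 fitted an additive model of region and sex over the 6 libraries, with variances moderated along the mean. The model leaves 2 residual degrees of freedom, with 3.49 prior degrees of freedom. Each comparison was adjusted by the Benjamini-Hochberg method over the kept genes, at a threshold of 0.05. A test of region by sex has 0 residual degrees of freedom and was not run. Because sex is a term in the model, the 3 libraries of each sex are matched across regions.

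Before the data were examined, 40 lists of genes, the tests, the alternatives and the rule for naming genes were fixed. The lists cover functions of the colon epithelium and other cell types that the samples could hold. Some genes belong to several lists, so list results are not all separate. The 36 lists with at least 4 kept genes were tested with camera at a preset correlation of 0.01, over 144 tests for the 4 comparisons. With a correlation estimated from the 2 residual degrees of freedom, camera called 0 lists in each comparison at the adjusted threshold. At an unadjusted p under 0.05 it then called 0, 0, 1 and 1 lists for distal against proximal, middle against proximal, distal against middle and female against male. The fry test, of whether a list moves on balance 1 way, also called 0 lists in each (lowest adjusted p 0.153, 0.153, 0.153 and 0.0876), and 11, 7, 2 and 1 at an unadjusted p under 0.05. The mixed fry test, of change in either direction, called 26, 20, 19 and 9.

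Genes were named by size: the 12 largest increases and 12 largest decreases between distal and proximal colon, and 6 of each in the other comparisons. They had to pass the threshold, move the same way in both sexes (or in all 3 regions) and have a mean FPKM of at least 5. Where fewer passed between the sexes, the next by p were taken. Up to 4 members per list were added, those past the threshold first, together with sex-linked and epithelial marker genes. Some genes that this rule takes are not reported here.

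The alternatives were a pseudocount of 0.1, no filter, a minimum of 5 FPKM, quantile normalization, median-ratio scaling, no variance trend, sex or region left out of the model, an estimated correlation, and each library left out in turn. Where a library was left out, the lone library of its region was assumed to vary like the others. Coordinates come from GENCODE M21 for mm10, matched by symbol for 23310 of 24346 entries. Figures were drawn with matplotlib 3.10.9 under Python 3.11.15. Genes with near-identical or related copies can exchange reads, so their values are uncertain. Among them are Reg3b and Reg3g and members of the Cyp2c, Ugt2b, Gsdmc, haemoglobin and H2-T families.

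The test was tried on simulated data, with 20 draws of 11815 genes of which 200 were changed. For distal against proximal colon, 83.0% of genes changed by 1 on the log2 scale and 96.2% of those changed by 2 were recovered. For distal against middle colon the shares were 82.3% and 96.0%. The simulated spread of each gene was its moderated one from the real fit, and no other effects of region or sex were put in. These shares can therefore overstate recovery in the real data. Unchanged genes made up 9.67% and 9.79% of the calls in these comparisons, above the nominal 5%. No gene was changed for middle against proximal colon and for female against male, where 8 and 10 of the 20 draws had false calls, with means of 1 and 1.4 calls per draw. A planted list of 20 genes changed by 1 on the log2 scale had a camera adjusted p of 7.9e-61 with the preset correlation and 0.219 with the estimated one. At the preset correlation 1 other of the 144 tests was called, and with the estimated correlation 0 were. The simulated genes were drawn independently of each other, so this run cannot show how the preset correlation performs where genes of a list move together. In the real data the estimated correlation ran from -0.17 for aquaporins to 0.90 for lymphocyte and 0.96 for ribosomal protein genes.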

Results

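RNA was sequenced from epithelial cells of the proximal, middle and distal colon of untreated wild-type C57BL/6J mice, an inbred laboratory strain, to compare expression along the length of the colon. The 6 libraries comprised 1 male and 1 female library from each of the 3 regions, giving n = 2 per region. The 3 libraries of each sex come from different regions, so n = 3 per sex does not count replicates of a sex. Each library listed FPKM, expression scaled to transcript length and library size, for the same 24346 gene entries. Total FPKM ranged from 546269 to 612818 per library, and 11170 to 11473 entries reached an FPKM of 1. The spacing of the lowest values placed the depth at 7.78 to 9.85 M fragments per library, as an estimate. The epithelial genes Epcam and Krt8 were at 743 to 873 FPKM and 3318 to 4008 FPKM in the 6 libraries. Lypd8, an antibacterial surface protein of colonocytes, was the most abundant entry in 5 libraries. The exception was the male proximal library, where the carbonic anhydrase Car1 took 3.43% of all FPKM. The labels do not state whether the 3 regions of a sex came from the same mice or from pools, so p-values measure the spread between these libraries, which may be partly technical.

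The first comparison, distal against proximal colon, asked which transcripts differ between the ends of the colon. HOX genes, transcription factors that pattern the body axis, differed in both directions. Hoxb13 (chromosome 11, 96194316 to 96197447) was 18.4 ± 25.2 FPKM in proximal and 492 ± 49.3 FPKM in distal colon (mean ± SD, n = 2), a log2 difference of 6.01 (SE 0.99, limma adjusted p = 0.018). Hoxd13 was 0.221 ± 0.312 FPKM in proximal and 49.0 ± 15.0 FPKM in distal colon (log2 difference 5.35, SE 0.15, limma adjusted p = 0.00040). Hoxd11 and Hoxd10 rose by 2.47 and 2.19 on the log2 scale. Hoxb6, by contrast, fell by 5.28 on the log2 scale (SE 0.41, limma adjusted p = 0.0028), from 43.8 ± 21.4 to 0.0899 ± 0.127 FPKM. Hoxb3, Hoxb7 and Hoxb8 fell by 3.75, 3.62 and 3.57 on the log2 scale. Of 15 kept members of the list of anterior and central HOX genes (paralogs 1 to 8), the counts in distal colon were 0 higher, 9 lower and 6 not past the threshold (0 higher and 9 lower adjusted over the list alone). By fitted value, whether called or not, 6 members were higher and 9 lower in distal colon. This list was lower in distal colon (camera adjusted p = 0.00025, and adjusted p = 0.852 with an estimated correlation). Of 10 kept members of the posterior list (paralogs 9 to 13), the counts were 5 higher, 1 lower and 4 not past the threshold (5 higher and 1 lower adjusted over the list alone). Posterior HOX genes were higher as a list (camera adjusted p = 0.0011, and adjusted p = 0.852 with an estimated correlation). The lower posterior member was Hoxb9 and the fifth higher one Hoxd12, both singled out after their values were seen. The 10 Hoxb genes lie on chromosome 11 between 96194316 and 96368256 and the 9 Hoxd genes on chromosome 2 between 74668310 and 74765142 (mm10).

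**Figure D1:**
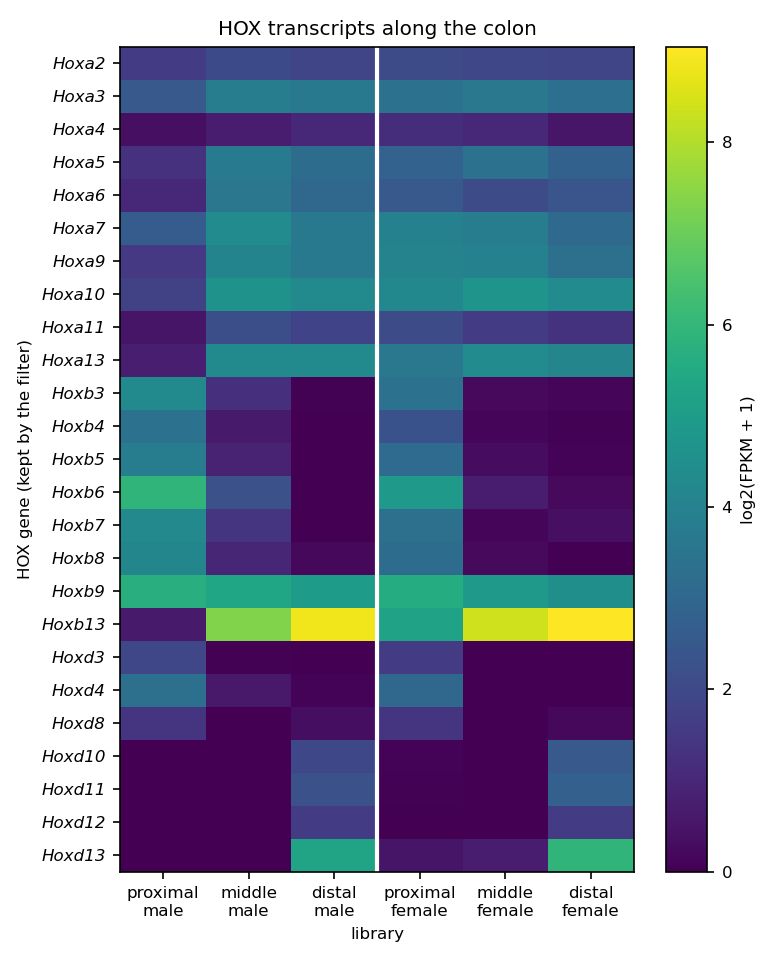
Heat map of log2(FPKM + 1) for the 25 HOX genes kept by the filter, in the male and the female libraries of each region. Hoxb3 to Hoxb8 are brightest in the proximal libraries, Hoxb13 reaches 457 and 527 FPKM in the distal libraries, and Hoxd13 stays below 1 FPKM outside them.

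Other transcription factors of the intestine also differed between the ends. Cdx2, a homeobox factor of intestinal identity at chromosome 5, 147300805 to 147307270, fell by 3.42 on the log2 scale (SE 0.26, limma adjusted p = 0.0028), from 130.1 ± 7.66 to 12.3 ± 7.08 FPKM (mean ± SD, n = 2). The intestine-specific homeobox gene Isx fell by 6.19 on the log2 scale (SE 0.26, limma adjusted p = 0.0011), from 135 ± 55.9 to 0.984 ± 1.21 FPKM. Foxa2 rose by 1.81. Tbx3, at 7.41 and 4.4 FPKM in the male and female proximal libraries, was listed at 0 in both distal libraries. Of the 18 kept members of the list of intestinal transcription factors, 3 higher, 3 lower and 12 not past the threshold (4 higher and 3 lower adjusted over the list alone) were counted. Besides Foxa2 the higher members were Klf5 and Elf3, named after their values were seen. Intestinal transcription factors as a list were not called (camera adjusted p = 0.857).

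The 12 largest decreases towards distal colon included the host defence genes Reg3b (chromosome 6, 78370657 to 78373466) and Reg3g (chromosome 6, 78466269 to 78468872), which encode antimicrobial lectins. They were at 341 and 116 FPKM in the male and 742 and 139.6 FPKM in the female proximal library, and both were listed at 0 in both distal libraries. Retnlb, which encodes a secreted goblet cell protein, fell by 5.91 on the log2 scale, from 81.1 ± 24.3 to 0.332 ± 0.106 FPKM (mean ± SD, n = 2; SE 0.49, limma adjusted p = 0.0032). Cyp4b1, a cytochrome P450, fell by 6.53 (SE 0.37, limma adjusted p = 0.0018), from 177 ± 130.4 to 0.660 ± 0.251 FPKM. The transcription factor Osr2, Plet1, Apol10a, Prap1, Sptssb and H2-T3 fell by 6.13, 6.07, 6.01, 5.84, 5.67 and 5.41 on the log2 scale. In the list of antimicrobial and host defence genes (20 kept members) 2 higher, 5 lower and 13 not past the threshold (4 higher and 5 lower adjusted over the list alone) were counted. The higher members were Pglyrp1 and Pla2g10, and Ang and Saa3 were lower besides Reg3b, Reg3g and Retnlb; Pglyrp1, Pla2g10 and Ang were named after their values were seen. Host defence genes as a list were not called (camera adjusted p = 0.882).

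The largest increases towards distal colon were led by Mptx1, a mucosal pentraxin, which rose by 8.55 on the log2 scale (SE 1.26, limma adjusted p = 0.013), from 0.208 FPKM in the male and 70.9 FPKM in the female proximal library to 3496 ± 120.1 FPKM in distal colon (mean ± SD, n = 2). Genes of electrogenic sodium absorption and potassium transport, which respond to aldosterone, were among them. Fxyd4 (chromosome 6, 117933559 to 117937692), a regulator of the sodium pump, went from 0.961 ± 1.36 to 401 ± 289 FPKM (log2 difference 7.66, SE 1.13, limma adjusted p = 0.013). Atp12a, the colonic proton-potassium pump, went from 1.54 ± 2.04 to 234 ± 4.59 FPKM (log2 difference 6.81, SE 0.55, limma adjusted p = 0.0031). Scnn1g, a subunit of the epithelial sodium channel, rose by 2.59. The aldosterone-responsive list (17 kept members) had 3 higher, 0 lower and 14 not past the threshold (6 higher and 0 lower adjusted over the list alone). Aldosterone-responsive genes were higher as a list (camera adjusted p = 0.019, and adjusted p = 0.852 with an estimated correlation). Tgm3, Sval1, Casp14, AI854703, B3gnt7 and Cyp2f2 rose by 6.08, 5.26, 5.18, 4.84, 4.70 and 4.18 on the log2 scale. The entry 5033404E19Rik, annotated as a transcribed processed pseudogene and therefore uncertain, was listed at 0 in both proximal libraries and at 18.05 and 13.3 FPKM in the distal libraries.

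**Figure D2:**
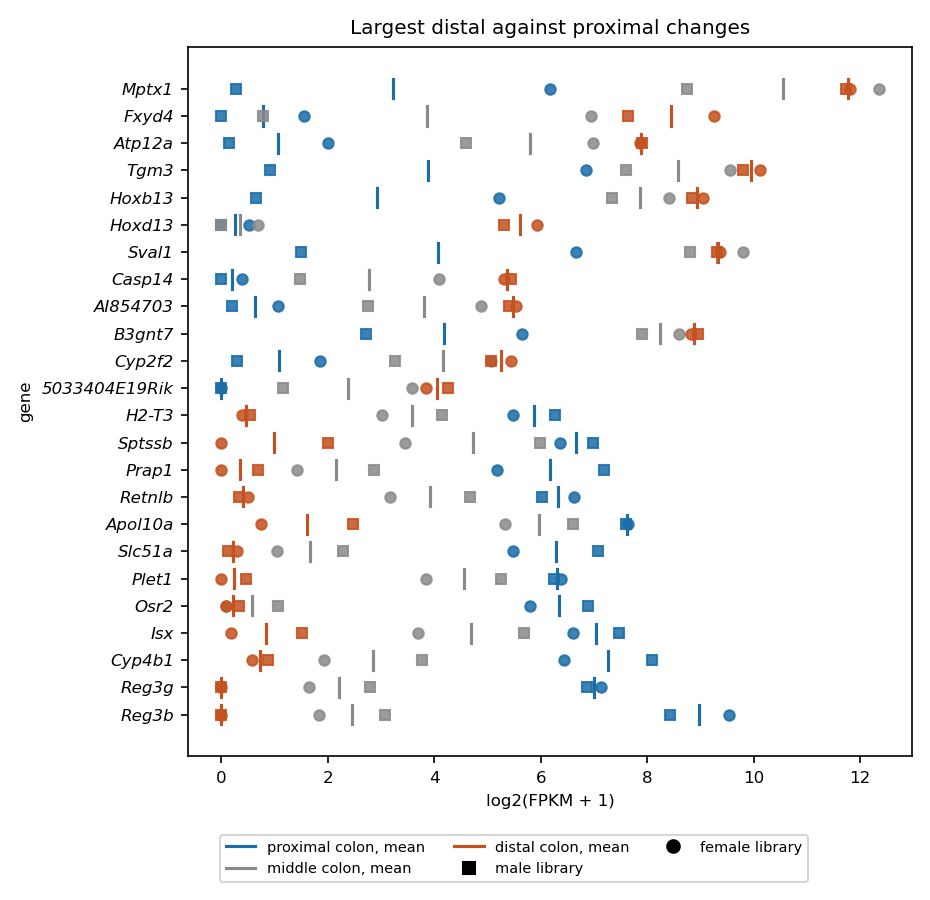
Expression as log2(FPKM + 1) of the 12 genes with the largest increase and the 12 with the largest decrease from proximal to distal colon, with squares for male libraries, circles for female libraries and vertical bars for the mean of each region. Reg3b and Reg3g are listed at 0 in both distal libraries, and the proximal values of Mptx1 are 0.208 FPKM in the male and 70.9 FPKM in the female library.

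Bile acid, fatty acid and drug metabolism genes were lower as lists in distal than in proximal colon (adjusted p = 0.852 for each with an estimated correlation). Pdk4 (chromosome 6, 5483351 to 5496309), a kinase that restrains glucose oxidation, fell by 3.26 on the log2 scale (SE 0.12, limma adjusted p = 0.00092), from 67.0 ± 39.2 to 5.91 ± 3.41 FPKM (mean ± SD, n = 2). Fabp2, an intestinal fatty acid-binding protein, fell by 4.58. Acaa1b, a peroxisomal thiolase, was at 39.6 and 7.16 FPKM in the male and female proximal libraries and listed at 0 in both distal libraries. For fatty acid oxidation and ketogenesis (25 kept members) the counts were 0 higher, 11 lower and 14 not past the threshold (1 higher and 15 lower adjusted over the list alone). Fatty acid oxidation genes were lower as a list (camera adjusted p = 1.4e-08, and adjusted p = 0.852 with an estimated correlation). The sodium-dependent bile acid transporter Slc10a2 fell by 4.31 (SE 0.54, limma adjusted p = 0.0086), from 67.8 ± 48.7 to 2.14 ± 1.26 FPKM. The subunits of the basolateral bile acid exporter, Slc51a and Slc51b, fell by 6.07 and 2.19. The bile acid receptor gene Nr1h4 fell by 1.23. For the bile acid list (8 kept members) the counts were 0 higher, 5 lower and 3 not past the threshold (0 higher and 5 lower adjusted over the list alone). Bile acid genes were lower as a list (camera adjusted p = 0.0026, and adjusted p = 0.852 with an estimated correlation). The fifth lower member was Abcc3, named after its values were seen. Among xenobiotic metabolism genes, Cyp2c65 fell by 4.89, Cyp2c68 rose by 3.58, and Ugt2b5, at 33.4 and 23.6 FPKM in the proximal libraries, was listed at 0 in both distal libraries. The counts for this list (37 kept members) were 4 higher, 16 lower and 17 not past the threshold (6 higher and 18 lower adjusted over the list alone). Xenobiotic metabolism genes were lower as a list (camera adjusted p = 0.00025, and adjusted p = 0.852 with an estimated correlation). The higher members besides Cyp2c68 were Cyp2d34, Nr1i3 and Adh1, named after their values were seen. Mature surface colonocyte genes (26 kept members) had 0 higher, 12 lower and 14 not past the threshold (4 higher and 15 lower adjusted over the list alone). Surface colonocyte genes were lower as a list (camera adjusted p = 0.00035, and adjusted p = 0.852 with an estimated correlation). Tmigd1 and Emp1 fell by 4.26 and 3.71. Slc51a and Slc51b belong to this list as well as to the bile acid list.

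Ion transport, mucus and glycosylation genes moved in both directions. Best2, a bicarbonate channel gene, rose by 3.09 on the log2 scale (SE 0.24, limma adjusted p = 0.0028), from 8.68 ± 2.49 to 79.8 ± 4.42 FPKM (mean ± SD, n = 2). The carbonic anhydrase genes Car12 and Car1 fell by 3.96 and 2.16 on the log2 scale, and the phosphate transporter gene Slc34a2 rose by 1.59. Muc2 (chromosome 7, 141690340 to 141754693), which encodes the main mucin of colonic mucus, fell by 2.31 (SE 0.23, limma adjusted p = 0.0049), from 1489.9 ± 166 to 299 ± 34.0 FPKM. The goblet cell factor Spdef and Guca2a fell by 1.97 and 1.69, whereas the trefoil factor Tff3 rose by 1.64. Glycosyltransferase genes split likewise: B3gnt7 rose, and B3gnt6 and Gcnt3 fell by 4.51 and 3.29. The electroneutral transport list (21 kept members) had 5 higher, 7 lower and 9 not past the threshold (9 higher and 9 lower adjusted over the list alone). The goblet cell and mucus list (22 kept members) had 7 higher, 4 lower and 11 not past the threshold (9 higher and 4 lower adjusted over the list alone). The glycan list (34 kept members) had 9 higher, 12 lower and 13 not past the threshold (12 higher and 14 lower adjusted over the list alone). Named after their values were seen, the other members were Slc26a2, Slc16a1 and Slc5a8 among the higher transport genes and Galnt12 among the lower mucus genes. None of these 3 lists was called in a direction (camera adjusted p = 0.638, 0.595 and 0.595).

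Some stem cell, proliferation, tuft cell and interferon response genes fell towards distal colon, 4 of 17, 7 of 28, 3 of 10 and 7 of 27 kept members. The Wnt target Cd44 fell by 2.94 on the log2 scale (SE 0.19, limma adjusted p = 0.0023), from 15.9 ± 3.24 to 1.25 ± 0.796 FPKM (mean ± SD, n = 2). Prom1 and Myc fell by 2.16 and 0.90. The stem cell and Wnt list (17 kept members) had 0 higher, 4 lower and 13 not past the threshold (2 higher and 8 lower adjusted over the list alone). Stem cell and Wnt genes were lower as a list (camera adjusted p = 0.048, and adjusted p = 0.852 with an estimated correlation). The other lower member was Slc12a2. Rrm2, a subunit of ribonucleotide reductase, fell by 1.30. Mcm4, Cdc20 and Ccnb1, genes of replication and mitosis, fell by 0.77, 0.76 and 0.76. The proliferation list (28 kept members) had 0 higher, 7 lower and 21 not past the threshold (0 higher and 16 lower adjusted over the list alone). Proliferation genes were lower as a list (camera adjusted p = 5.4e-07, and adjusted p = 0.852 with an estimated correlation). Tuft cell genes were near the lower limit of the values (at most 1.96 FPKM on average over the 6 libraries). Trpm5 fell by 1.09. Ltc4s was listed at 0 in both distal libraries and at 4.85 and 1.45 FPKM in the proximal ones. For this list (10 kept members) the counts were 0 higher, 3 lower and 7 not past the threshold (0 higher and 7 lower adjusted over the list alone). Tuft cell genes were lower as a list (camera adjusted p = 0.0034, and adjusted p = 0.852 with an estimated correlation). Irf7, Oasl1, Ifit1 and Rsad2 of the type I interferon response fell by 1.70, 1.44, 1.43 and 1.21. Their list (27 kept members) had 0 higher, 7 lower and 20 not past the threshold (0 higher and 7 lower adjusted over the list alone). Interferon response genes were lower as a list (camera adjusted p = 0.043, and adjusted p = 0.852 with an estimated correlation). Among lymphocyte transcripts, Gzma, a granzyme of cytotoxic lymphocytes, fell by 2.90 (SE 0.25, limma adjusted p = 0.0036). The T cell and intraepithelial lymphocyte list (13 kept members) had 0 higher, 6 lower and 7 not past the threshold (0 higher and 11 lower adjusted over the list alone). Lymphocyte genes were lower as a list (camera adjusted p = 3.7e-06, and adjusted p = 0.852 with an estimated correlation). The summed FPKM of this list was 114 in the male and 52.1 in the female proximal library, against 15.0 and 21.2 in the distal libraries.

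**Figure D3:**
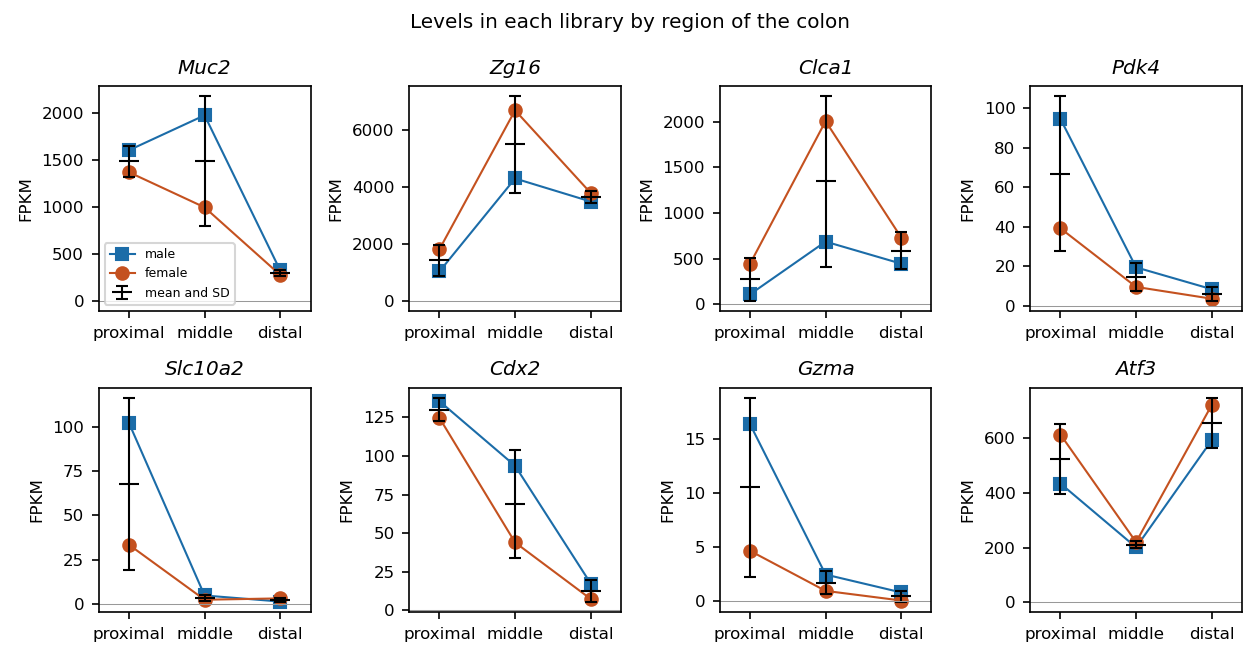
FPKM of 8 genes in each library by region of the colon, with squares for male libraries, circles for female libraries and black bars for the mean and SD of each region (n = 2). Pdk4, Cdx2 and Gzma are lowest in distal colon in both sexes, Zg16 and Clca1 are highest in middle colon, and Atf3 is lowest in middle colon.

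All 39 ribosomal protein genes had higher fitted values in distal colon, with a median log2 difference of 0.28. Among them, limma called 0 members at the adjusted threshold and 2 at an unadjusted p under 0.05, and 0 higher and 0 lower adjusted over the list alone (fry mixed adjusted p = 0.33). Ribosomal protein genes were higher as a list (camera adjusted p = 0.00027, and adjusted p = 0.873 with an estimated correlation). Over all genes, limma called 1668 of 11815 kept genes between distal and proximal colon, 765 higher and 903 lower in distal, all in the same direction in both sexes. In this model opposite changes in the sexes count as residual spread, so such genes can hardly be called. The shared direction of called genes is therefore no separate check. A change of at least 2-fold was seen for 395 of the higher and 499 of the lower genes. Without the male distal library the count was 340, and without the female distal library 770. Of the 117 genes that the naming rule takes for this comparison, 67 and 85 were called in these runs. Trpm5 was not called with quantile normalization (limma adjusted p = 0.080), nor Sval1 with a pseudocount of 0.1 (0.052). Leaving out single libraries ended the calls of the stem cell and Wnt list (adjusted p up to 0.16) and of the interferon list (up to 0.56) without the male middle, female proximal, female middle or female distal library, and that of the ribosomal list without the male distal library (0.17).

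Between middle and proximal colon, mucus genes were higher in the middle as a list (adjusted p = 0.852 with an estimated correlation). Clca1, a secreted goblet cell protein, rose by 2.43 on the log2 scale (SE 0.31, limma adjusted p = 0.029), from 273 ± 236 to 1347 ± 935 FPKM (mean ± SD, n = 2). Zg16, a lectin of the mucus layer, went from 1414 ± 549.8 to 5481 ± 1690.4 FPKM (log2 difference 1.98, SE 0.24, limma adjusted p = 0.028). Fcgbp and Capn9 rose by 1.95 and 1.45. The goblet cell and mucus list (22 kept members) had 5 higher, 0 lower and 17 not past the threshold (11 higher and 1 lower adjusted over the list alone). Mucus genes were higher as a list (camera adjusted p = 6.4e-07, and adjusted p = 0.852 with an estimated correlation). The fifth higher member was Bcas1, named after its values were seen. Muc2 was at 1489.9 ± 166 FPKM in proximal and 1489 ± 695 FPKM in middle colon, going from 1607 to 1980 FPKM in males and from 1373 to 997 FPKM in females. Atp12a rose by 4.72 (SE 0.55, limma adjusted p = 0.027). The aldosterone-responsive list had 1 higher, 0 lower and 16 not past the threshold (1 higher and 0 lower adjusted over the list alone). Aldosterone-responsive genes were higher as a list (camera adjusted p = 0.0057, and adjusted p = 0.852 with an estimated correlation). Other large increases were in Spink1 (3.41), the hormone gene Insl5 (3.39) and the protease gene Ctse (3.32). The pseudogene entry Apoo-ps rose by 3.24, and the small nucleolar RNA Snora21 was at 20.1 and 16.0 FPKM in the middle libraries and listed at 0 in the other 4. Both entries are uncertain, the first because it can share reads with its parent gene and the second because of its short length.

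Bile acid, fatty acid oxidation and anterior and central HOX genes were lower as lists in middle than in proximal colon (adjusted p = 0.852 for each with an estimated correlation). Slc10a2 fell by 3.79 on the log2 scale (SE 0.54, limma adjusted p = 0.037), from 67.8 ± 48.7 to 3.47 ± 1.70 FPKM (mean ± SD, n = 2). Slc51a, Slc51b and Nr1h4 fell by 4.62, 1.44 and 1.22. The bile acid list (8 kept members) had 0 higher, 4 lower and 4 not past the threshold (0 higher and 7 lower adjusted over the list alone). Bile acid genes were lower as a list (camera adjusted p = 2.1e-06, and adjusted p = 0.852 with an estimated correlation). Acaa1b, Pdk4 and Angptl4 fell by 3.40, 2.08 and 2.02. The fatty acid oxidation list had 0 higher, 5 lower and 20 not past the threshold (0 higher and 14 lower adjusted over the list alone). Fatty acid oxidation genes were lower as a list (camera adjusted p = 2.5e-10, and adjusted p = 0.852 with an estimated correlation). Hoxb6, Hoxb3, Hoxb8 and Hoxb7 fell by 3.93, 3.13, 3.08 and 3.03. Anterior and central HOX genes had 0 higher, 9 lower and 6 not past the threshold (1 higher and 9 lower adjusted over the list alone). By fitted value 6 members were higher and 9 lower in middle colon. Anterior and central HOX genes were lower as a list (camera adjusted p = 0.00010, and adjusted p = 0.852 with an estimated correlation). Posterior HOX genes were not called as a list (camera adjusted p = 0.22), with 6 fitted values higher and 3 lower. Xenobiotic genes, among which Cyp4b1 fell by 4.41 and Cyp2c68 rose by 2.91, had 3 higher, 9 lower and 25 not past the threshold (4 higher and 17 lower adjusted over the list alone). Xenobiotic metabolism genes were lower as a list (camera adjusted p = 3.8e-06, and adjusted p = 0.852 with an estimated correlation). Surface colonocyte genes, among them Slc51a, Cyp2c55 and Slc51b, had 0 higher, 5 lower and 21 not past the threshold (2 higher and 9 lower adjusted over the list alone). Slc51a and Slc51b are also in the bile acid list, so the results of both lists overlap. Surface colonocyte genes were lower as a list (camera adjusted p = 0.0024, and adjusted p = 0.852 with an estimated correlation). Reg3b and Reg3g fell by 6.53 and 4.78, Osr2 by 5.77 and the calcium-binding protein gene S100g by 4.36. Named after their values were seen, further members past the threshold were Guca2b among colonocyte genes, and Nr1i3 and Adh1 among the higher xenobiotic genes.

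Single immediate early and lymphocyte genes, 4 of 25 and 1 of 13 kept members, also fell from proximal to middle colon. Fosl1, Egr2, Atf3 and Fosb fell by 2.16, 2.12, 1.29 and 1.07 on the log2 scale, with Atf3 going from 524 ± 127 to 210.4 ± 13.6 FPKM (mean ± SD, n = 2; limma adjusted p = 0.026). The list of immediate early and dissociation stress genes (25 kept members) had 0 higher, 4 lower and 21 not past the threshold (1 higher and 6 lower adjusted over the list alone). Immediate early genes were lower as a list (camera adjusted p = 0.0047, and adjusted p = 0.852 with an estimated correlation). Gzma fell by 1.96, and the lymphocyte list had 0 higher, 1 lower and 12 not past the threshold (0 higher and 6 lower adjusted over the list alone). Lymphocyte genes were lower as a list (camera adjusted p = 6.4e-07, and adjusted p = 0.852 with an estimated correlation). Cd44 fell by 1.78, and the stem cell and Wnt list had 0 higher, 1 lower and 16 not past the threshold (0 higher and 1 lower adjusted over the list alone). Stem cell and Wnt genes were lower as a list (camera adjusted p = 0.018, and adjusted p = 0.852 with an estimated correlation). For the proliferation list, lower in middle colon with a median log2 difference of 0.04 in males and -0.57 in females (camera adjusted p = 0.00084, and adjusted p = 0.873 with an estimated correlation), limma called 0 members at the adjusted threshold and 4 at an unadjusted p under 0.05, and 0 higher and 0 lower adjusted over the list alone (fry mixed adjusted p = 0.443). In all, limma called 289 genes, 141 higher and 148 lower in middle colon, all in the same direction in both sexes, which the model favours. Without the female middle library limma called 0 genes (1402 at an unadjusted p under 0.05), without the male middle library 39, and without the female proximal library 806. The count was 4 with no filter on low values, 187 without the variance trend and 24 with sex left out of the model. With a pseudocount of 0.1, Hoxb3, Hoxb6, Hoxb7, Slc10a2, Gzma, Fosb, Ctse and Spink1 were not called (limma adjusted p = 0.058, 0.075, 0.13, 0.055, 0.075, 0.055, 0.057 and 0.060), nor was Spink1 with quantile normalization (0.057). Leaving out the female proximal library ended the calls of the HOX (adjusted p = 0.051), colonocyte (0.24), immediate early (0.51), stem cell (up to 0.17, also without the male middle library) and proliferation lists (up to 0.97, also without the female middle library).

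Between distal and middle colon, Muc2 and several glycosyltransferase genes were lower and posterior Hoxd genes higher in distal colon. Muc2 fell by 2.23 on the log2 scale (SE 0.23, limma adjusted p = 0.036), from 1489 ± 695 to 299 ± 34.0 FPKM (mean ± SD, n = 2). Hoxd13 rose by 5.26 (SE 0.15, limma adjusted p = 0.0011), from 0.311 ± 0.439 to 49.0 ± 15.0 FPKM. Hoxd11 and Hoxd10, listed at 0 in both middle libraries, were at 3.71 and 2.85 FPKM in the male and 5.78 and 4.76 FPKM in the female distal library. Isx and Cdx2 fell by 3.85 and 2.41. The mucin glycosyltransferase gene B3gnt6 fell by 3.68 (SE 0.34, limma adjusted p = 0.026), from 17.5 ± 11.7 to 0.305 ± 0.233 FPKM. B4galnt1 and B4galnt2 fell by 3.28 and 1.22. Apol10a, Plet1 and Sptssb fell by 4.36, 4.31 and 3.72. The activity-regulated genes Nr4a1, Atf3 and Arc rose by 1.68, 1.63 and 1.71, with Atf3 going from 210.4 ± 13.6 to 658 ± 91.2 FPKM. The phosphatase gene Pdp1 and the ion channel gene Trpv3 rose by 1.73 and 1.63.

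By list, goblet cell and mucus genes (22 kept members) had 0 higher, 1 lower and 21 not past the threshold (1 higher and 12 lower adjusted over the list alone) between distal and middle colon. Mucus genes were lower as a list (camera adjusted p = 1.4e-08, and adjusted p = 0.852 with an estimated correlation). Glycan genes (34 kept members) had 0 higher, 3 lower and 31 not past the threshold (5 higher and 13 lower adjusted over the list alone). Glycan genes were lower as a list (camera adjusted p = 8.1e-05, and adjusted p = 0.852 with an estimated correlation). Posterior HOX genes (10 kept members) had 3 higher, 0 lower and 7 not past the threshold (4 higher and 0 lower adjusted over the list alone). Posterior HOX genes were higher as a list (camera adjusted p = 0.0056, and adjusted p = 0.852 with an estimated correlation). Immediate early genes had 2 higher, 0 lower and 23 not past the threshold (11 higher and 5 lower adjusted over the list alone). Immediate early genes were higher as a list (camera adjusted p = 0.0011, and adjusted p = 0.852 with an estimated correlation). Surface colonocyte genes had 0 higher, 1 lower and 25 not past the threshold (0 higher and 9 lower adjusted over the list alone). Surface colonocyte genes were lower as a list (camera adjusted p = 5.6e-05, and adjusted p = 0.852 with an estimated correlation). The fatty acid oxidation list, in which Pdk4 fell by 1.18, had 0 higher, 2 lower and 23 not past the threshold (0 higher and 4 lower adjusted over the list alone). Fatty acid oxidation genes were lower as a list (camera adjusted p = 0.0031, and adjusted p = 0.852 with an estimated correlation). Host defence genes had 0 higher, 1 lower and 19 not past the threshold (0 higher and 6 lower adjusted over the list alone), and Saa3 fell by 1.48 on the log2 scale. Host defence genes were lower as a list (camera adjusted p = 0.0045, and adjusted p = 0.852 with an estimated correlation). Enteroendocrine genes (16 kept members) had 0 higher, 1 lower and 15 not past the threshold (0 higher and 2 lower adjusted over the list alone), the proglucagon gene Gcg falling by 1.71. Enteroendocrine genes were lower as a list (camera adjusted p = 0.011, and adjusted p = 0.852 with an estimated correlation). Tuft cell genes were lower in distal colon as a list (camera adjusted p = 5.5e-07, and adjusted p = 0.852 with an estimated correlation). Of them, limma called 0 members at the adjusted threshold and 9 at an unadjusted p under 0.05, and 0 higher and 8 lower adjusted over the list alone (fry mixed adjusted p = 0.016). For interferon response genes, also lower (camera adjusted p = 2.0e-05, and adjusted p = 0.852 with an estimated correlation), limma called 0 members at the adjusted threshold and 6 at an unadjusted p under 0.05, and 0 higher and 2 lower adjusted over the list alone (fry mixed adjusted p = 0.032). For proliferation genes, lower as a list (camera adjusted p = 2.7e-05, and adjusted p = 0.852 with an estimated correlation), limma called 0 members at the adjusted threshold and 6 at an unadjusted p under 0.05, and 0 higher and 0 lower adjusted over the list alone (fry mixed adjusted p = 0.383). For ribosomal protein genes, higher as a list with a median log2 difference of 0.18, and of 0.42 in males and -0.06 in females (camera adjusted p = 0.00048, and adjusted p = 0.873 with an estimated correlation), limma called 0 members at the adjusted threshold and 0 at an unadjusted p under 0.05, and 0 higher and 0 lower adjusted over the list alone (fry mixed adjusted p = 0.507). For anterior and central HOX genes, lower as a list (camera adjusted p = 0.027, and adjusted p = 0.852 with an estimated correlation), limma called 0 members at the adjusted threshold and 1 at an unadjusted p under 0.05, and 0 higher and 0 lower adjusted over the list alone (fry mixed adjusted p = 0.675).

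The distal against middle comparison had the fewest genes of the 3 between regions. limma called 59, of which 13 were higher and 46 lower in distal colon, all in the same direction in both sexes, which the model favours. Without the male distal library limma called 0 genes (753 at an unadjusted p under 0.05), without the male middle, female distal and female middle libraries 1, 7 and 36, and without either proximal library 406. The count was 2 with no filter on low values, 29 without the variance trend and 17 with sex left out. Muc2 was not called with quantile normalization (log2 difference -2.35, limma adjusted p = 0.077) or without the male middle, male distal or female distal library (0.093, 0.28 and 0.13). Sptssb was not called with quantile normalization (0.055) or a pseudocount of 0.1 (0.10), nor Trpv3 (0.095), Hoxd10 (0.085), Hoxd11 (0.067) and Saa3 (0.12) with that pseudocount. Saa3 was also not called with a minimum of 5 FPKM (0.084). Of the 13 lists called at the preset correlation, the goblet, glycan, tuft and colonocyte lists were called without each library in turn. The other 9 each lost their call without at least 1 library, at adjusted p of up to 0.72 for the ribosomal list without the male middle or male distal library, where its direction turned in 1 of the 6 runs. The anterior HOX list lost its call without the male middle or male distal library (up to 0.49), the posterior HOX list without the male proximal, male distal or female middle library (0.14), and the enteroendocrine and fatty acid lists without the male distal or female middle library (0.35 and 0.20). The host defence and interferon lists lost theirs without the female distal library (0.25 and 0.074), the proliferation list without the male middle library (0.15) and the immediate early list without the male distal library (0.053).

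Regional differences were compared between the sexes, which share no library. Across the 11815 kept genes, the distal minus proximal log2 difference in males correlated with that in females (Pearson r = 0.782, Spearman rho = 0.636). For middle minus proximal these values were 0.527 and 0.355, and for distal minus middle 0.545 and 0.388; genes are not independent replicates, so no p is attached. Of 589 genes at least 2-fold higher in distal than proximal colon in males, 92.2% were higher in females too and 66.0% had the female middle value between the ends. Of 641 genes at least 2-fold lower in males, these shares were 96.6% and 79.9%. With the choice made in females, 407 higher genes gave 96.3% and 79.9% in males and 617 lower genes 93.4% and 70.2%. Unrelated values would give 50% and 16.7%. A test for any difference among the 3 regions (limma moderated F test) called 1042 genes (366 with no filter on low values and 454 with sex left out). Without the male distal library it called 291, without the female distal library 521, and without the male or female middle library 586 and 589. On the first principal component, which held 66.2% of the variance, the proximal, middle and distal libraries lay at -51.3, -7.71 and 31.2 for males and at -30.3, 19.4 and 38.7 for females.

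**Figure D4:**
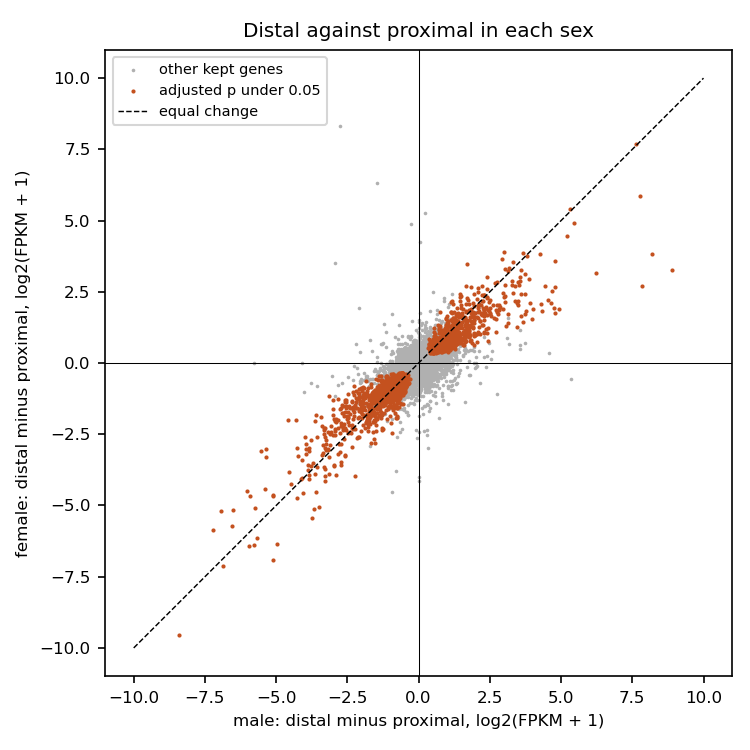
Log2 difference of FPKM + 1 between distal and proximal colon in the male libraries (horizontal axis) and in the female libraries (vertical axis), with each point a kept gene, orange where limma called it and the dashed line at equal change. The 1668 called genes lie to the lower left and upper right of the origin, since the model hardly calls genes that move in opposite directions. Across all 11815 genes r is 0.782.

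The female against male comparison first checked the labels. Xist, which is expressed from the inactive X chromosome, was at 82.2, 70.8 and 66.9 FPKM in the female proximal, middle and distal libraries and at most 0.1003 FPKM in the male libraries. The Y-linked genes Ddx3y, Eif2s3y, Kdm5d and Uty were at 5.12 to 39.1 FPKM in the male libraries, listed at 0 in the female proximal and distal libraries, and at 0.0604 to 0.258 FPKM in the female middle library. These were the 5 genes that limma called: Xist rose by 6.15 on the log2 scale (SE 0.10, limma adjusted p = 5.2e-05). Eif2s3y, Kdm5d, Ddx3y and Uty fell by 5.12, 3.48, 3.33 and 2.64. The X-linked genes Eif2s3x and Kdm6a, which escape inactivation, had differences of 0.70 and 0.67 in all 3 regions in the same direction but did not pass (limma adjusted p = 0.191 and 0.297). The list of genes escaping inactivation (7 kept members) had 1 higher, 0 lower and 6 not past the threshold (5 higher and 0 lower adjusted over the list alone), and the member past it was Xist. Genes escaping inactivation were higher as a list (camera adjusted p = 2.1e-09, and adjusted p = 0.852 with an estimated correlation). Of genes on other chromosomes with a mean FPKM of at least 5, Pdk4 had the lowest adjusted p, at 40.8 ± 47.0 FPKM in males and 17.4 ± 19.1 FPKM in females (mean ± SD over the 3 regions, log2 difference -1.09, SE 0.09, limma adjusted p = 0.082). This SD holds the differences between regions. The p-values of this comparison measure how the sex difference varies between regions, not the spread between mice. All male libraries are replicate 1 and all female libraries replicate 2. Their estimated depths were 7.78 to 7.94 M and 8.88 to 9.85 M fragments. Any other difference between these sets of libraries cannot be told apart from sex, for genes or for lists. Sgk2 and Dgat2 had differences of -1.02 and -0.82, and Ccl28, Fam134b and the X-linked gene Slc6a14 of 0.68, 0.64 and 0.66, none of them past the threshold.

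Of the other lists, ribosomal protein genes were higher in females as a list (camera adjusted p = 4.3e-10, and adjusted p = 0.852 with an estimated correlation), where limma called 0 members at the adjusted threshold and 4 at an unadjusted p under 0.05, and 0 higher and 0 lower adjusted over the list alone (fry mixed adjusted p = 0.277). Proliferation genes were lower in females as a list (camera adjusted p = 4.6e-07, and adjusted p = 0.852 with an estimated correlation), where limma called 0 members at the adjusted threshold and 10 at an unadjusted p under 0.05, and 0 higher and 0 lower adjusted over the list alone (fry mixed adjusted p = 0.27). Fatty acid oxidation genes were lower as a list (camera adjusted p = 6.4e-07, and adjusted p = 0.852 with an estimated correlation), where limma called 0 members at the adjusted threshold and 8 at an unadjusted p under 0.05, and 0 higher and 4 lower adjusted over the list alone (fry mixed adjusted p = 0.021). Cholesterol synthesis genes were lower as a list (camera adjusted p = 0.00084, and adjusted p = 0.852 with an estimated correlation), where limma called 0 members at the adjusted threshold and 4 at an unadjusted p under 0.05, and 0 higher and 0 lower adjusted over the list alone (fry mixed adjusted p = 0.595). Surface colonocyte genes were lower as a list (camera adjusted p = 0.0085, and adjusted p = 0.852 with an estimated correlation), where limma called 0 members at the adjusted threshold and 5 at an unadjusted p under 0.05, and 0 higher and 3 lower adjusted over the list alone (fry mixed adjusted p = 0.013). Retinoid metabolism genes were lower as a list (camera adjusted p = 0.028, and adjusted p = 0.852 with an estimated correlation), where limma called 0 members at the adjusted threshold and 2 at an unadjusted p under 0.05, and 0 higher and 1 lower adjusted over the list alone (fry mixed adjusted p = 0.040). Erythroid genes, markers of red blood cells, were lower as a list (camera adjusted p = 0.0037, and adjusted p = 0.852 with an estimated correlation), where limma called 0 members at the adjusted threshold and 4 at an unadjusted p under 0.05, and 0 higher and 4 lower adjusted over the list alone (fry mixed adjusted p = 0.179). The median female minus male difference in proximal, middle and distal colon was 0.06, -0.56 and -0.41 for proliferation genes, 0.19, -0.44 and -0.24 for cholesterol synthesis genes and 0.00026, -0.48 and -0.14 for colonocyte genes. For the ribosomal, fatty acid, retinoid and erythroid lists it had the same sign in all 3 regions. On the first principal component the female libraries lay further towards distal, at -30.3, 19.4 and 38.7 against -51.3, -7.71 and 31.2 for males. The ribosomal, proliferation, fatty acid and colonocyte lists were called in the same directions for distal against proximal colon, and with an estimated correlation in neither comparison (adjusted p = 0.852 to 0.873). The summed FPKM of the erythroid list was 293, 218 and 265 in the male and 91.4, 200.006 and 68.7 in the female proximal, middle and distal libraries. At the preset correlation, without either proximal library camera called 18 lists and without either distal library 13, against 8 with all libraries. The gene count was 2 without the male middle library, 24 without the male proximal, 25 without the female proximal, 9 without the male distal and 10 without the female distal library. Uty was not called with a minimum of 5 FPKM (limma adjusted p = 0.12). Without the male or female middle library the colonocyte (adjusted p up to 0.13) and cholesterol (0.26) lists lost their calls, and without either proximal library the retinoid list did (0.16).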

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

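The comparisons in this part were chosen after the values of each sex were seen, by the rule that both sexes, or the 3 regions, moved in opposite directions. None of these differences was tested, since each sex has 1 library per region.

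Reg4, a secreted lectin, differed by -2.89 on the log2 scale between middle and proximal colon in males and by 5.26 in females, so that female minus male was 8.15. Its FPKM was 397, 52.7 and 459.8 in the male and 10.2, 430.5 and 430.2 in the female proximal, middle and distal libraries. Slc37a2, a sugar phosphate transporter gene, went the same ways, by -2.91 and 4.82 (female minus male 7.72), at 145, 18.5 and 121.2 FPKM in males and 3.01, 111.9 and 116 FPKM in females. The sterol hydroxylase gene Cyp27a1 differed by -1.71 and 1.10 for the same comparison (female minus male 2.80). The water channel gene Aqp4 differed by 2.75 between distal and proximal colon in males and by -1.07 in females (female minus male -3.82). Of 8656 genes with a mean FPKM of at least 5, 6, 12 and 3 differed at least 2-fold in opposite directions in males and females for distal against proximal, middle against proximal and distal against middle.

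The median of proliferation genes between middle and proximal colon was lower in females than in males by 0.62 on the log2 scale (female minus male -0.62). For ribosomal protein genes between distal and middle colon, female minus male was -0.48. Between females and males, the median difference of proliferation genes spanned 0.63 from the highest to the lowest of the 3 regions, that of surface colonocyte genes 0.48 and that of cholesterol synthesis genes 0.64.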

How the results depend on the processing

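Of the alternatives, the run without small RNA entries was chosen after seeing the data and the others before. Between distal and proximal colon the gene count stayed within 1.5 times its value of 1668 in every setting except 2 of the 6 left-out libraries. With no filter on low values the counts were 4 for middle against proximal, 2 for distal against middle and 366 for any region. Without the variance trend they were 187 and 29 for the first 2 of these. With no replicate block, that is with sex, which matches the 3 libraries of a sex across regions, left out of the model, they were 24, 17 and 454. The cause was not tested. With an estimated correlation in camera the lists called were 0 for distal against proximal, 0 for middle against proximal, 0 for distal against middle and 0 for female against male, in place of 13, 11, 13 and 8. That correlation rests on 2 residual degrees of freedom.

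With 1 library left out, counts ranged from 340 (male distal) to 1583 for distal against proximal, from 0 (female middle) to 806 (female proximal) for middle against proximal, from 0 (male distal) to 406 (either proximal) for distal against middle, from 291 (male distal) to 1385 for any region and from 2 (male middle) to 25 (female proximal) for female against male. At the 2 counts of 0, limma called 1402 and 753 genes at an unadjusted p under 0.05. Lists ranged from 11 to 16, 11 to 15, 9 to 18 and, between the sexes, 11 to 18 (either proximal). These runs have fewer libraries, and why single libraries mattered as they did is open: the cause was not tested. The genes named as past the threshold kept their sign in each of these runs, which share their remaining libraries with the full fit. The correlation of the sexes was 0.782 and between 0.765 and 0.804 under the alternatives. For single named genes, 361 results lost their call over the 6 runs that leave out 1 library and 102 gained one. In the other settings, 109 results lost their call with no filter, 86 with sex left out, 31 without the trend, 23 with a pseudocount of 0.1, 8 with quantile normalization and 5 with the 5 FPKM minimum, and 0 reversed. Without small RNA entries the counts were 1736, 372, 68, 1167 and 5. The estimated depth, 7.78 to 9.85 M fragments, limits genes near 1 FPKM.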

Other observations

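All tests of explanations in this part were chosen after the results they address were seen.

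Among lists that camera did not call between distal and proximal colon, single genes still differed. Retinoid metabolism genes had 2 higher, 4 lower and 8 not past the threshold (3 higher and 7 lower adjusted over the list alone), with a camera adjusted p of 0.103. Among them Aldh1a1 and Lrat fell by 3.12 and 2.21 on the log2 scale and Rdh16 rose by 2.70. Gasdermins, which form membrane pores, had 3 higher, 1 lower and 1 not past the threshold (4 higher and 1 lower adjusted over the list alone), with a camera adjusted p of 0.108. Gsdmc3 and Gsdmc4 rose by 2.25 and 1.68. Enteroendocrine genes had 2 higher, 5 lower and 9 not past the threshold (3 higher and 7 lower adjusted over the list alone), with a camera adjusted p of 0.203. They included Insl5, which rose from 8.48 ± 7.98 to 60.0 ± 4.85 FPKM (mean ± SD, n = 2), and Gcg and Chgb, which fell by 1.90 and 2.04. Nts was at 10.7 and 5.03 FPKM in the proximal libraries and listed at 0 in both distal ones. Genes typical of small intestine had 3 higher, 4 lower and 4 not past the threshold (5 higher and 5 lower adjusted over the list alone), with a camera adjusted p of 0.662. They included Alpi, which fell by 3.52, and Slc15a1, which rose by 3.34. The tight junction genes Cldn15 and Cldn8 differed by -1.93 and 1.67, and the steroid enzyme genes Hsd3b3 and Hsd3b2 by -1.89 and -1.85. Aqp1 fell by 1.71. Other members of these lists past the threshold included Aldh1a3 (higher), Rarg and Rxra (lower) for retinoids, Gsdmd (higher) and Dfna5 (lower) for gasdermins, Pyy (higher), Cck and Pcsk1 (lower) for enteroendocrine genes, and Slc5a1 (higher) and Sis, Fabp2 and Apob (lower) for small intestine. Of these, Rarg, Rxra, Pyy, Cck, Pcsk1, Slc5a1 and Apob were named after their values were seen. For aquaporins and for host defence genes the median log2 difference was positive (0.10 and 0.28) and the direction of the camera test negative.

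Some lists of other cell types were low. The lists of B and plasma cells and of enteric neurons and glia had 0 kept members, and those of fibroblasts and endothelial cells 3 and 2, so none of these 4 was tested. Summed FPKM per library was at most 1.87, 3.04, 12.9 and 4.93 for these lists. Amd1 and Amd2, singled out after their values were seen, were at 14.6 and 14.7 FPKM in the male proximal library and at 0.0542 and 30.2 FPKM in the male middle library. Their sum was 26.5 to 34.3 FPKM in the 6 libraries, so the split between these near-identical entries is uncertain.

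The first pattern weighed is that the female libraries lay further towards distal than the male libraries of the same region. On the first principal component the gap was widest in middle colon. The female middle library correlated across genes at 0.982 with the male distal library and at 0.975 with the male middle library. The male middle library in turn correlated at 0.976 with the female proximal library. A candidate explanation is that the female middle segment was taken further along the colon, or the male middle segment less far. Across genes, female minus male in middle colon correlated at 0.521 with distal minus proximal in the other 4 libraries. This value cannot tell which of the middle libraries moved. For proximal colon the axis was distal minus middle, and for distal colon middle minus proximal. These correlations were 0.0738 and 0.0774 (0.163 and 0.136, against 0.686 for middle, over the 1840 genes with a mean FPKM of at least 50). Neither axis is the local one or the one used for middle, so the values cannot be ranked against it. They cannot tell a shift of position from none there. The male and female proximal libraries correlated at 0.975, as did the middle pair, and lay at -51.3 and -30.3 on the first principal component. The first rule asked for more than 0.2 in all 3 regions, was not met, and was rewritten after the values were seen. Female minus male in middle colon holds no proximal library, so the male proximal library standing apart could not produce that difference. The middle difference correlated at 0.551 with distal minus proximal in females. This value does not test whether the male proximal library stood apart in the proximal pair or on the principal component. Sex of the mice stays open, with 1 library per sex and region. In the fit of all libraries limma called 0 genes off the X and Y chromosomes, which cannot settle it.

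The second pattern is the fall of Muc2 from middle to distal colon, by 2.23 on the log2 scale (SE 0.23). Fewer goblet cells as the whole cause would lower the other 21 members of the list alike, if each were expressed in goblet cells alone. Their median was -0.56, from -1.40 for Guca2a to 0.48 for Muc13. The list also takes in mucus genes that other cells may express, so these values cannot exclude a lower share of goblet cells. Scaling of the libraries is argued against as the source of the size, which was -2.24 with median-ratio scaling and -2.35 with quantile normalization, although the call was lost under the latter (SE 0.33 against 0.23, limma adjusted p = 0.077 against 0.036). Beside a lower share of goblet cells, lower Muc2 transcript per goblet cell in distal colon may be held as a hypothesis, and was not tested by itself. Counts of Muc2 transcripts in single goblet cells of middle and distal colon would decide it. The call was also lost without the male middle, male distal or female distal library (limma adjusted p = 0.093, 0.28 and 0.13).

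The third pattern is the lower level of lymphocyte transcripts in distal colon. All 13 kept members were lower in distal than in proximal colon in both sexes, as fewer intraepithelial lymphocytes among the distal cells could give. The summed FPKM fell by 2.93 on the log2 scale in males and by 1.30 in females, and the most abundant member, Ccl5, averaged 13.6 FPKM. Less carry-over of every non-epithelial cell type cannot be told apart from this. Fibroblast and endothelial sums differed by 0.25 in males and -0.57 in females, at no more than 3.74 FPKM per member. In better expressed lists, kept members lower and higher in distal colon numbered 3 and 1 for smooth muscle, 3 and 2 for myeloid and 5 and 0 for erythroid genes. None of these lists was called (camera adjusted p = 0.108, 0.497 and 0.275). The summed FPKM of the myeloid list rose, from 36.8 to 44.0 in males and from 33.6 to 47.5 in females. The smooth muscle genes Mylk and Tagln fell by 0.97 and 0.61 and the myeloid gene Tyrobp by 1.63, whereas the myeloid gene Cd14 rose by 1.19, and erythroid sums went from 293 to 265 FPKM in males and from 91.4 to 68.7 FPKM in females.

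For female against male, the 6 libraries make 10 splits into 3 and 3, too few for a share under 0.05. The split by sex called 5 genes and the highest other split 4, so that only the split by sex gave as many genes (1 of 10). The 4 genes came from splits that are the same fit and rest on the proximal libraries alone. The 5 genes called by sex are Xist and the Y-linked genes of the label check. Their count therefore says nothing on other differences between the sexes. By sex 8 lists were called and the highest other split called 16, with 7 splits giving as many lists, the split by sex included. With region in the model, a split that puts both libraries of a region on the same side rests on the libraries of 1 region, and recurs as an identical fit. The 10 splits are therefore not all separate references. Besides the split by sex, those with 1 library of each region on each side called 0 genes each and 5, 8 and 16 lists.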
